A study of Bos taurus with 30 samples.

How the data were processed

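The study measured RNA of bovine lymphocytes on Agilent bovine oligonucleotide arrays with 1 colour, Cyanine 3. Of the 15 animals, 8 had received prednisolone and 7 were controls, and each was sampled at 2 times, T1 and T2, which gave 30 arrays with 1 animal per array and no pooling. The values deposited by the authors were linear intensities, positive numbers from 1.62 to 1067622. Per the series text, each array was scanned at 2 sensitivities, which Feature Extraction 9.5 joined before it detrended the signal and subtracted the background. The submitters' processing notes name R 2.11.1. The arrays were already close in scale, and the method of normalization between arrays, and the rule by which 17.16% of the cells were null, are not given in the sources used here. Null cells were more common among dim features: 29.6% of cells in features with a median intensity of 100 or less and 1.7% in brighter ones.

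The design, chosen before the data were examined like the comparisons, gene lists and naming rule below, assumed log2 values. The table held linear intensities, so, as the design foresaw, each array was scaled to the 75th percentile of the features with a value on all arrays, raised to a floor of 1.82 (percentile 1, log2 0.867; 0.035% of values lay at it) and logged. The scaling moved no array by more than 0.044 log2 units. Subtracting each array's 75th percentile, listed as another setting to try, is therefore what was done here and was not run separately. Of 44407 features, 6954 had 1 gene in the platform annotation, none had several and 37453 had none. Symbols were updated through accessions for 5432 features, kept as current symbols for 1358, updated through synonyms for 158 and left under the platform's name for 6, which gave 3269 genes. The reference tables served only for names, and no coordinates were used.

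The design took a gene's brightest probe. Every gene had an even number of features, and pairs of features behaved as duplicate spots (median gap 0.078 log2 units over 3098 genes with 2 features, median correlation over arrays 0.90 for 1508 bright pairs). Both spots were therefore averaged, and for genes with more features those within 0.25 log2 units of the brightest were, a choice made after the values were seen, and the brightest feature alone was run as an alternative. Genes in the lowest 25% by mean intensity, or with a value on fewer than 4 arrays of a group, were left out, and 2446 genes were tested, 205 of them with uncharacterised LOC symbols. Of these, 216 had a missing value on some array (0.87% of values), and each fit used the arrays with a value.

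Differences were fitted per gene with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p; differences are on the log2 scale with limma's standard error (SE). Treatment was compared at T1, at T2 and on each animal's mean of both times, T2 was compared with T1 within controls and within treated animals, and the interaction of treatment and time was fitted over all 30 arrays. The animals' numbers link T1 and T2. The deviations of an animal's arrays from their group means correlated at 0.104 to 0.613 across features (median 0.380), and 13 of 15 animals correlated best with their own number, so the animal entered as a block in an alternative of each comparison. No label names the slide, position or hybridisation batch of an array, so no batch was modelled. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

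Gene lists for glucocorticoid-induced and glucocorticoid-repressed genes, blood cell types, immune responses and metabolism were tested where at least 5 members were measured, with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Missing values of tested genes were filled with their fitted group mean for camera alone. An exact two-sided permutation test compared the animals' list means, by relabelling animals or, within a group, by swapping an animal's times, and p-values were adjusted over the lists of a comparison. "Adjusted over the list alone" means Benjamini-Hochberg over the list's measured genes. An animal shows a direction when it lies on that side of the control mean, or, for a time comparison, when its own T2 minus T1 difference has that sign (for the interaction, beyond the mean control difference). Genes were named by rule: for treatment at T1, at T2 and by time the 10 largest rises and 10 largest falls that passed, or, where fewer passed, those of smallest p up to 5, stated as not passing; for the others the same with 5 and 3; the list members that passed, over all genes or else over the list alone, up to 4 per list; and 7 glucocorticoid target and receptor genes. Of those 7, only ZBTB16 and NR3C1 were measured under a name, and the other 5 are not analysed here. A gene named outside the rule is stated as such. Most named genes were picked by their p or fold in these same arrays. Counts of animals with their direction therefore describe them and add no separate support.

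The tests were run on simulated data, with 200 of 2446 genes shifted. Each gene's spread was as in the real arrays, and genes were independent of one another. The 2 arrays of an animal were drawn independently too, unlike the real ones (median correlation 0.380). Rates for comparisons that use both times may therefore not carry over to the real arrays. Shifts of 0.5, 1 and 2 log2 units were recovered in 52.2%, 91.0% and 95.5% of genes at T1, in 50.7%, 88.1% and 97.0% at T2, and in 32.8%, 74.6% and 90.9% for treatment by time, and false calls made up 4.0% to 7.4% of calls over the 6 comparisons. In each comparison 1 list, the 45 measured oxidative phosphorylation genes, was shifted by 0.4 in simulated data. Camera called it each time and called none of 20 unshifted lists. Smaller lists were not shifted. Members of real lists correlate, at an estimated 0.232 for the glucocorticoid-repressed list at T2. These runs on independent genes therefore do not show how often camera at its preset correlation errs on real lists. The alternatives tried were other scalings and dim-gene filters, other summaries of features, other models of the spread, the animal block, a fold threshold and leaving out each animal in turn. Added after the data were seen were the values as deposited, quantile normalization over complete features, the brightest feature alone, genes with all values, the number of null features as a covariate, a floor at an intensity of 16, leaving out animals 28 and 32 together and, for the gene lists, leaving out animal 30.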

Results

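Gene expression was measured in lymphocytes of 15 cattle (Bos taurus) on single-colour microarrays, on which the Cyanine 3-labelled RNA of 1 animal hybridises to each array. Prednisolone, a synthetic glucocorticoid, was given by mouth to 8 animals, at a daily 30 mg per animal over 35 days, and 7 animals served as controls. Each animal was sampled at T1 and at T2, which gave 30 arrays in 4 groups: 8 treated and 7 control animals at each time. The labels do not say where T1 and T2 lie relative to the dosing, and they name the slaughterhouse as the place of collection. Each array gave a value for 34506 to 38801 of the 44407 features, and the median intensity over the 23055 features with a value on all arrays lay between 996.7 and 1040. An array's median correlation with its own group lay between 0.976 and 0.989. After naming and a filter on dim genes, 2446 genes were tested. The number of arrays, not a read depth, limits the precision.

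On the first principal component, with 23.3% of the variance over 2230 genes, the 8 treated animals at T2 lay together at 9.16 to 14.32. The control arrays of both times lay at -5.73 to 4.68. The treated animals at T1 lay at -24.76 to -3.60, and animals 28 and 32 stood apart from the other treated animals there, at -22.90 and -24.76.

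**Figure D1:**
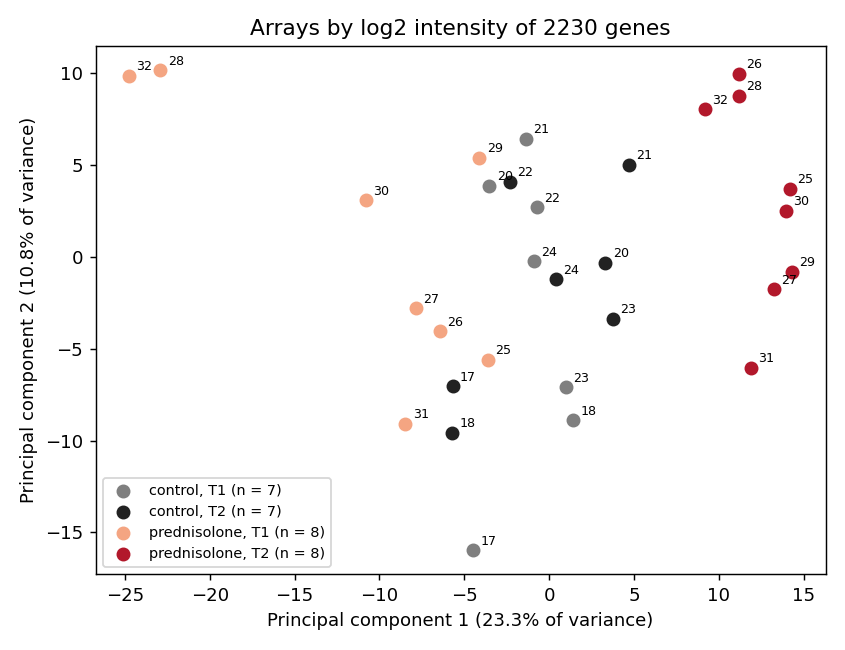
Scores of the 30 arrays on the first (horizontal) and second (vertical) principal components of the log2 intensities of 2230 genes, with 23.3% and 10.8% of the variance; each point is 1 array, coloured by group and marked with the animal's number. The treated arrays of T2 lie at 9.16 or above on the horizontal axis, and those of T1 at -3.60 or below.

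The comparison at T1 asked how treated and control animals differed at the first sampling. Among 2446 genes, 2 rose and 5 fell in the treated animals, while 522 had an unadjusted p under 0.05. RPL27, which encodes a protein of the large ribosomal subunit, rose by 0.92 on the log2 scale (SE 0.156, adjusted p = 0.0314), from 9.28 ± 0.22 in controls (SD, n = 7) to 10.20 ± 0.37 in treated animals (SD, n = 8). ATP5F1D, a subunit of the mitochondrial ATP synthase, rose by 0.59 (SE 0.116, adjusted p = 0.0422). IL15, a cytokine that sustains natural killer and memory T cells, fell by 1.11 (SE 0.211, adjusted p = 0.0422) at a dim level, from 5.44 ± 0.43 (SD, n = 7) to 4.32 ± 0.40 (SD, n = 7). The chromatin protein HMGB2 fell by 0.64 (SE 0.107, adjusted p = 0.0314). ARNT, the partner of the aryl hydrocarbon receptor, fell by 0.75 (SE 0.147), and the genes of a pepsinogen, PGA5, and an amylase, AMY2B, fell by 0.96 (SE 0.177) and 0.44 (SE 0.087), each at an adjusted p of 0.0422. For 6 of these 7 genes all 8 treated animals lay on the side of the change relative to the control mean, and for IL15 all 7 with a value did.

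Other genes stood apart at T1 without passing over all genes in the main fit, though many of them passed with the animal as a block, as given below. SPP1, which encodes the secreted protein osteopontin, differed by 4.20 (SE 0.907, adjusted p = 0.0586), with all 8 treated animals above the control mean. CD14, the lipopolysaccharide co-receptor of monocytes, differed by 1.44 (SE 0.319, adjusted p = 0.0586), also in 8 of 8 animals. Of 10 measured glucocorticoid-induced genes none passed over all genes, while adjusted over the list alone 2 did: CXCR4, a chemokine receptor, at 0.88 (SE 0.213), and the transcription factor CEBPD at 0.60 (SE 0.204). Of 14 pattern recognition genes, 3 passed adjusted over the list alone: CD14, the adaptor TIRAP at 0.50 (SE 0.130), and the flagellin receptor TLR5 at -1.22 (SE 0.349). Single members passed adjusted over the list alone in the lists of T cell activation (IFNG, -0.97, SE 0.299), MHC class II presentation (BOLA-DYB, 0.59, SE 0.169), oxidative phosphorylation (COX7C, 0.57, SE 0.141), unfolded protein response (XBP1, 0.41, SE 0.116) and cholesterol synthesis (CYP51A1, 0.62, SE 0.144). In glycolysis HK1 (-0.35, SE 0.095) and LDHA (0.47, SE 0.161) did. MECR, of mitochondrial fatty acid synthesis, and GAL, which encodes galanin, differed by 0.74 (SE 0.158) and 0.64 (SE 0.140), each at an adjusted p of 0.0586. The glucocorticoid receptor gene NR3C1 differed by -0.12 (SE 0.128, adjusted p = 0.6241) and ZBTB16, a glucocorticoid target in many tissues, by 0.19 (SE 0.256, adjusted p = 0.6882). No list passed, the lowest adjusted p from camera being 0.2014, for ribosomal proteins and for natural killer and cytotoxic genes. The count of 7 depended on the spread model and the scaling. With the animal as a block over both times 233 genes passed (152 higher, 81 lower), and 252 (164 higher, 88 lower) in 1 fit of all 30 arrays without the block. Quantile normalization gave 118 (14 higher, 104 lower), around a median of all genes that this scaling shifted to -0.094. Over complete features it gave 24 higher and 22 lower. Among the 233 were SPP1 (adjusted p = 0.0081), CD14 (0.0151), CXCR4 (0.0158), TIRAP (0.0172), TLR5 (0.0203), COX7C (0.0082), XBP1 (0.0161), CYP51A1 (0.0099), HK1 (0.0268), LDHA (0.0266), MECR (0.0081) and GAL (0.0204). Without animals 28 and 32 no gene passed in limma, with 350 at an unadjusted p under 0.05, and camera called the glucocorticoid-repressed list lower (adjusted p = 0.0183), though not with an estimated correlation (adjusted p = 0.8488), and its exact permutation test gave p = 0.2273.

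At T2 more genes passed: 262 rose and 183 fell in the treated animals, 30 of them more than 2-fold. Together they made up 18.2% of the genes tested, the share beside which counts of list members at T2 are to be read. The contrast with the 7 genes at T1 was smaller by other measures. At an unadjusted p under 0.05 there were 522 genes at T1 and 719 at T2, and 1 fit of all 30 arrays called 252 and 373. The excess of rises depended on the scaling, with 213 rises and 205 falls in the values as deposited, 195 and 175 with quantile normalization over complete features, and 229 and 112 with quantile normalization over all features. The immediate early genes, transcription factors and an RNA-binding regulator that cells switch on within minutes of a stimulus, rose together, all 4 that were measured passing. FOS rose by 1.77 (SE 0.156, adjusted p = 1.80e-05), from 12.18 ± 0.17 in controls (SD, n = 7) to 13.95 ± 0.40 (SD, n = 8), EGR1 by 1.60 (SE 0.291, adjusted p = 0.0018), JUN by 0.84 (SE 0.086, adjusted p = 5.99e-05) and ZFP36, whose product destabilises cytokine mRNAs, by 0.58 (SE 0.105, adjusted p = 0.0018), each in 8 of 8 treated animals. CCL2, a monocyte-attracting chemokine, fell by 3.76 (SE 0.887, adjusted p = 0.0120) and had a value in 5 of the 8 treated animals, each below the control mean. These values were dim, and null cells were more common among dim features, so the size of this fold is uncertain. THBS1, which encodes the matrix protein thrombospondin, fell by 2.03 (SE 0.438, adjusted p = 0.0050) and PTGS2, the inducible cyclooxygenase, by 1.92 (SE 0.529, adjusted p = 0.0205), both in 8 of 8 animals.

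Among glucocorticoid-repressed inflammatory genes at T2, 4 of 19 measured genes fell and none rose: CCL2, PTGS2, IL2 (-0.88, SE 0.172) and the chemokine CCL3 (-0.95, SE 0.260), and 7 fell adjusted over the list alone. The list's median was -0.60, lower than that of the other genes by camera (adjusted p = 0.0071), a call lost at adjusted p = 0.927 with an estimated correlation. An exact permutation test of the animals' list means gave p = 0.0402, or 0.1963 adjusted over the lists. Heat shock chaperones were higher, with a median of 0.22 and camera's adjusted p = 0.0466 (adjusted p = 0.927 with an estimated correlation, and 0.0683 with quantile normalization). Of 8 measured chaperones, 2 rose, AHSA1 (0.42, SE 0.067) and DNAJA1 (0.38, SE 0.104). The exact permutation test of this list gave p = 1.55e-04, the smallest that 15 animals allow, or 0.0034 adjusted over the lists. Of 10 glucocorticoid-induced genes, NFKBIA, the inhibitor of NF-kB, rose by 0.45 (SE 0.128), CEBPD rose by 0.78 (SE 0.244) and SLA, an adaptor that dampens T cell receptor signals, fell by 0.48 (SE 0.148). The list as a whole was not called (camera adjusted p = 0.9032). ZBTB16 (-0.64, SE 0.312, adjusted p = 0.1920) and NR3C1 (0.24, SE 0.096, adjusted p = 0.1017, and 0.0409 with array weights) did not pass.

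Immune genes moved in both directions at T2. Of 14 pattern recognition genes, 4 rose and 3 fell: the RNA receptor TLR7 rose by 1.48 (SE 0.265), TLR5 by 1.21 (SE 0.294) and MYD88, the adaptor shared by most of these receptors, by 0.36 (SE 0.087), while TIRAP fell by 0.44 (SE 0.110) and CD14 fell by 1.11 (SE 0.339, adjusted p = 0.0336, 6 of 8 animals). The other 7 measured monocyte markers had a median difference of 0.000 and none passed. Of 12 trafficking genes, CCR7, the receptor for homing to lymph nodes, fell by 0.69 (SE 0.142) and CXCR5, the follicle-homing receptor, by 0.56 (SE 0.168). Of 9 T cell activation genes, ICOS, a co-stimulatory receptor, fell by 0.52 (SE 0.097), IL2 fell as above, and the early activation marker CD69 rose by 0.57 (SE 0.162). Of 10 T cell markers, CD2 rose by 0.32 (SE 0.10) and CCR7 fell. NCR1, a natural killer cell receptor, rose by 0.70 (SE 0.226) as 1 of 9 cytotoxic genes, and MX1, an antiviral protein, rose by 1.29 (SE 0.338) as 1 of 10 interferon response genes.

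In metabolism at T2, 2 of 6 cholesterol synthesis genes rose, CYP51A1 by 0.65 (SE 0.124) and FDPS by 0.43 (SE 0.127), and 2 of 7 fatty acid oxidation genes rose, HADHA by 0.26 (SE 0.078) and ACADVL by 0.25 (SE 0.075). Of 45 oxidative phosphorylation genes, NDUFS1 (0.43, SE 0.142) and NDUFA6 (0.29, SE 0.096) rose and NDUFA9 fell (-0.32, SE 0.061), and the chaperone HSPA5 of the endoplasmic reticulum rose by 0.30 (SE 0.094). No ribosomal, glycolytic, cell cycle, neutrophil, erythroid or housekeeping gene passed at T2. Other large rises were those of the small heat shock protein HSPB8 (1.76, SE 0.480), HMMR, a hyaluronan receptor (1.41, SE 0.255), TRAF3IP3, an adaptor of lymphocytes (1.35, SE 0.155), GRO1, a chemokine under its platform name (1.32, SE 0.386), and of the histamine receptor HRH1 (1.3, SE 0.420) and the histamine-degrading enzyme HNMT (1.3, SE 0.297). ARG2, a mitochondrial arginase, fell by 1.58 (SE 0.330), the carbonic anhydrase CA4 by 1.35 (SE 0.333) and KIT, the stem cell factor receptor, by 1.28 (SE 0.316).

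PRM1 (-3.37, SE 0.784), SPP1 (-2.83, SE 0.768), the glucose transporter SLC5A1 (-2.71, SE 0.359) and TNFAIP6 (-1.30, SE 0.399) fell too, but lay near the lowest intensities, so the size of their folds at T2 is uncertain. With intensities under 16 raised to 16, SPP1 (adjusted p = 0.1509), SLC5A1 (adjusted p = 0.0854) and TNFAIP6 (adjusted p = 0.1109) no longer passed. With the mean of all features of a gene, MYD88 (0.12, adjusted p = 0.6825) and CXCR5 (-0.29, adjusted p = 0.2347) did not pass, nor did NDUFA6 (adjusted p = 0.0507), and CXCR5 did not with quantile normalization either (-0.44, adjusted p = 0.2865). With the animal as a block over both times HSPB8 (adjusted p = 0.0769), PTGS2 (0.0892), TNFAIP6 (0.0718), CCL3 (0.1431), CD2 (0.0617), CXCR5 (0.0668), NCR1 (0.0817), CD69 (0.1463), NDUFA6 (0.1390), AHSA1 (0.0529), HSPA5 (0.0617), HADHA (0.1263) and ACADVL (0.0601) no longer passed at T2. A single fit of all 30 arrays without the block ended the same calls, and those of NFKBIA (adjusted p = 0.0516) and GRO1 (adjusted p = 0.0565). Without animals 28 and 32, CCL2 (-3.54, adjusted p = 0.0566), GRO1 (0.0885), HRH1 (0.1191), NFKBIA (0.0802), CEBPD (0.1210), CXCR5 (0.0611), CD69 (0.0808), NDUFS1 (0.0915), NDUFA6 (0.0957), HSPA5 (0.0892), HADHA (0.0855) and ACADVL (0.0607) did not pass.

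**Figure D2:**
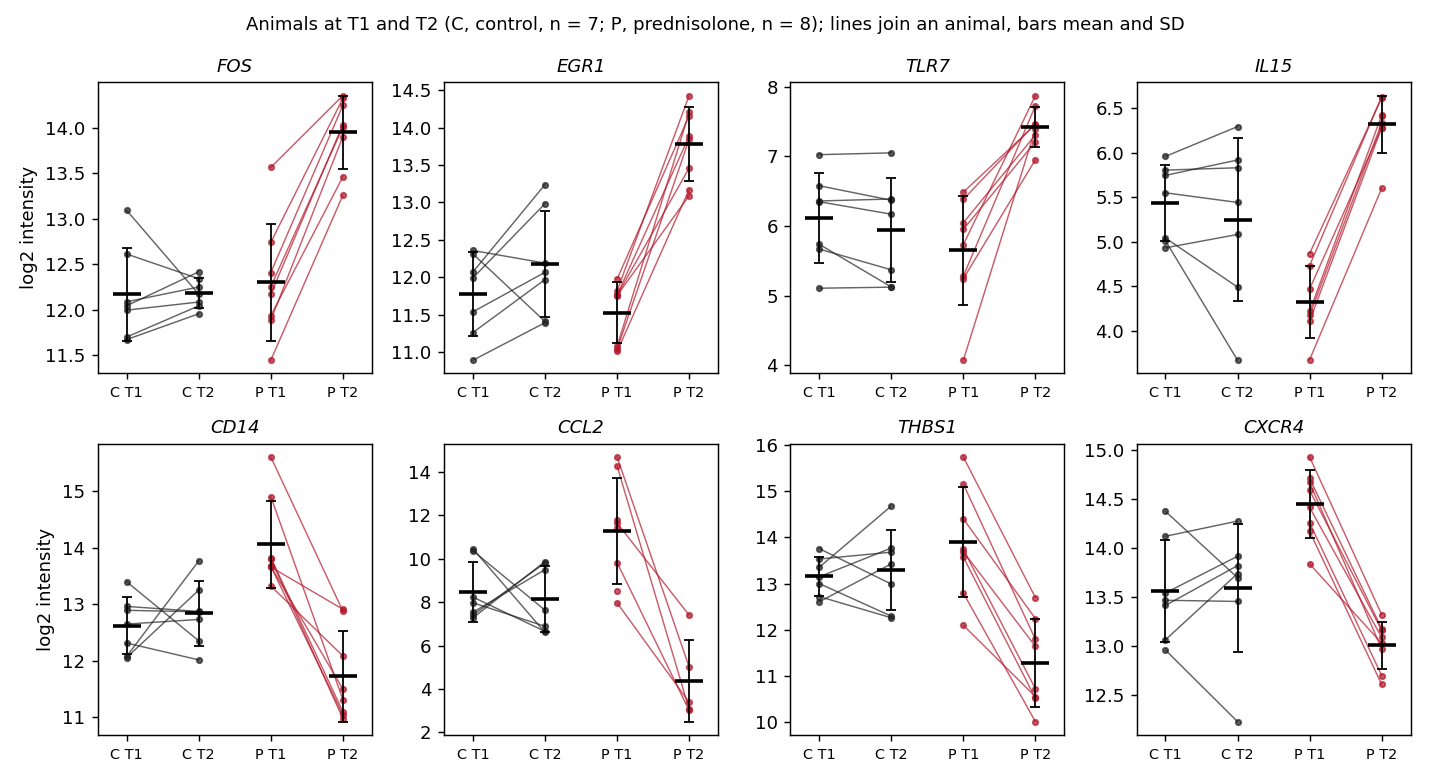
Log2 intensity (vertical axes) of 8 genes in control (C, n = 7) and treated (P, n = 8) animals at T1 and T2; points are animals, lines join an animal's samples, bars give the mean and SD, and null values are not drawn, which leaves 5 treated animals for CCL2 at T2. FOS, EGR1, TLR7 and IL15 lie higher and CD14, CCL2, THBS1 and CXCR4 lower at T2 than at T1 in the treated animals.

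Averaged over both times, 26 genes rose and 29 fell in treated animals, none of them more than 2-fold, out of 470 at an unadjusted p under 0.05. FOS rose by 0.95 (SE 0.203, adjusted p = 0.0274), TRAF3IP3 by 0.79 (SE 0.113, adjusted p = 0.0025) and CYP51A1, a demethylase of sterol synthesis, by 0.64 (SE 0.10, adjusted p = 0.0048), each in 8 of 8 treated animals. EIF4A1, an RNA helicase of translation initiation, fell by 0.51 (SE 0.056, adjusted p = 3.78e-04), and ARNT fell by 0.46 (SE 0.084, adjusted p = 0.0148), again in 8 of 8. HDHD3 (0.56, SE 0.132) and NPFF (0.50, SE 0.079) rose, and TRIB2 (-0.56, SE 0.121), FBXO8 (-0.47, SE 0.098) and PDCL (-0.46, SE 0.065) fell. RPL27 rose by 0.44 (SE 0.073) as 1 of 39 ribosomal genes and CD2 by 0.34 (SE 0.081) as 1 of 10 T cell genes. CEBPD (0.69, SE 0.196), IL2 (-0.65, SE 0.163), MX1 (0.89, SE 0.245) and HADHA (0.35, SE 0.093) passed adjusted over the list alone. The glucocorticoid-repressed list was lower (median -0.37) and the heat shock (0.24) and ribosomal (0.07) lists higher, each at camera's adjusted p = 0.0151. With an estimated correlation none of these calls held, at adjusted p = 0.8084 for the glucocorticoid-repressed and heat shock lists and adjusted p = 0.9113 for the ribosomal list, which was also lost with quantile normalization (0.1818). Treated animal 30 had the highest heat shock list at T1, at 1.85 with the other treated animals at -0.16 to 0.34. The exact permutation test, adjusted over the lists, gave 0.5305 for the glucocorticoid-repressed list and 0.1190 for the ribosomal list, so neither passed. It gave 0.0120 for the heat shock list and 0.0120 for the cholesterol synthesis list, whose mean difference was 0.20. Camera did not call the cholesterol synthesis list (adjusted p = 0.0860), though it did with quantile normalization (0.0495). ZBTB16 (-0.22, SE 0.251) and NR3C1 (0.06, SE 0.086) did not pass. The 55 genes became 87 with the animal as a block, with 49 shared, and 19 without animals 28 and 32, when FOS (adjusted p = 0.0525), HDHD3 (0.0560), TRIB2 (0.0640), ARNT (0.0525) and CD2 (0.1084) no longer passed. Of the 55 genes, 46 also passed at T2, 19 higher and 27 lower in both, where independent calls would give 2.78 and 2.17. The T2 arrays enter both comparisons, so a shared direction is built in.

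The comparison of T2 with T1 in the 7 control animals asked what changed over time without the drug. No gene passed in the main fit, which does not pair an animal's 2 times, with 245 at an unadjusted p under 0.05. With the animal as a block 3 genes passed, with 415 at an unadjusted p under 0.05. The interferon-induced IFITM1 stood 1.02 higher at T2 (SE 0.191, adjusted p = 0.1172), JMJD6 0.48 (SE 0.108) and the actin-capping gene CAPZB 0.48 (SE 0.112). SLA stood at -0.59 (SE 0.119, adjusted p = 0.1387), ZBTB43 at -0.37 (SE 0.076) and COL6A2 at -0.35 (SE 0.075). All 7 control animals showed the direction of the mean for each of these 6 genes, which their choice by smallest p in these same arrays makes likely. Adjusted over the list alone, SLA, CD2 (0.40, SE 0.112), NFKBIZ (-0.47, SE 0.142), BIRC5, an inhibitor of apoptosis in dividing cells (0.82, SE 0.218), and 3 of 8 chaperones passed: DNAJB1 (-0.64, SE 0.147), HSPB1 (0.32, SE 0.091) and DNAJA1 (-0.35, SE 0.103). ZBTB16 (0.17, SE 0.356) and NR3C1 (-0.32, SE 0.117) did not pass. No list was called. The glucocorticoid-repressed list, with a median of -0.33, had an adjusted p of 0.0547 from camera and 0.0464 with the animal as a block, against adjusted p = 0.9425 with an estimated correlation.

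In the 8 treated animals, 528 genes rose and 388 fell from T1 to T2, 106 of them more than 2-fold. Together they made up 37.4% of the genes tested, the share beside which counts of list members over time in treated animals are to be read. The values as deposited gave 465 rises and 466 falls and quantile normalization 455 and 304. The transcription factors NFE2 and EGR1 rose by 2.32 (SE 0.290, adjusted p = 2.11e-05) and 2.26 (SE 0.214, adjusted p = 2.36e-06), and IL15 by 2.0 (SE 0.179, adjusted p = 2.36e-06). TLR5 rose by 1.87 (SE 0.275) and TLR7 by 1.78 (SE 0.277). SPP1 fell by 6.98 (SE 0.802, adjusted p = 1.09e-05), from 8.62 ± 2.42 (SD, n = 8) to 1.64 ± 0.30 (SD, n = 8), near the lowest intensities, so the size of its fold is uncertain, though it still passed with intensities under 16 raised to 16. CCL2 fell by 6.90 (SE 1.176, adjusted p = 5.40e-04), from 11.27 ± 2.45 (SD, n = 8) to 4.37 ± 1.88 (SD, n = 5). It was dim at T2 and null in the other treated animals, so the size of this fold is uncertain as well. The neutrophil-attracting chemokine CXCL5 fell by 3.62 (SE 0.731, adjusted p = 0.0011). SLC5A1 (-2.86, SE 0.280) and IL6 (-3.00, SE 1.080, adjusted p = 0.0454) fell at dim levels, IL6 in 3 of the 4 animals with both values and not with the animal as a block (adjusted p = 0.1843). The other genes named in this paragraph moved in the stated direction in all animals with both values. At T1, CCL2 was highest in animals 28 and 32, at 14.28 and 14.70.

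Of 19 glucocorticoid-repressed genes, 6 fell from T1 to T2 in treated animals and 1, IL18 (0.57, SE 0.190), rose; TNF fell by 1.51 (SE 0.391), CCL3 by 1.56 (SE 0.432) and IL1B by 1.53 (SE 0.541). Of 10 glucocorticoid-induced genes, 4 fell and none rose: CXCR4 by 1.44 (SE 0.146), SLA by 1.25 (SE 0.180), ZBTB16 by 0.66 (SE 0.211) and GADD45B by 0.54 (SE 0.134). The means of the glucocorticoid-repressed (-0.92) and glucocorticoid-induced (-0.44) lists fell in 8 of 8 animals (exact permutation p = 0.0078 for each, the smallest 8 pairs allow), and neither passed adjusted over the lists (0.0859). Animals 28 and 32 carried part of the size: without them the means were -0.61 and -0.28, in 6 of 6 animals (exact permutation p = 0.0312, or 0.2292 adjusted over the lists, for each). In controls the glucocorticoid-repressed mean was lower too, at -0.395 in 6 of 7 animals, and the glucocorticoid-induced one at -0.068 in 4 of 7. The groups' changes differed at an exact permutation p of 0.2378 and 0.0232, or 0.3736 and 0.2790 adjusted over the lists. In treated animals all 4 immediate early genes rose, FOS by 1.65 (SE 0.251), JUN by 0.86 (SE 0.081) and ZFP36 by 0.48 (SE 0.156). Of 12 trafficking genes 4 rose and 4 fell, with falls of CXCR4, CCR7 (-1.30, SE 0.213) and CXCR5 (-0.96, SE 0.216) and a rise of the integrin chain ITGB1 (0.34, SE 0.080). Of 9 T cell activation genes 3 fell, ICOS (-1.04, SE 0.194), CTLA4 (-0.67, SE 0.145) and IL4 (-0.64, SE 0.243), and CD40LG, the ligand that T cells show to B cells, rose (0.80, SE 0.199). Of 10 T cell markers 4 rose, among them CD6 (0.81, SE 0.177), CD2 (0.36, SE 0.111) and CD3G (0.34, SE 0.107), and CCR7 fell. CR2, a complement receptor of B cells, rose by 0.78 (SE 0.210).

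Of 14 pattern recognition genes 5 rose and 4 fell over time in treated animals, with a rise of MYD88 (0.46, SE 0.067) and falls of CD14 (-2.33, SE 0.370) and TIRAP (-0.87, SE 0.119). CD14 was the 1 of 8 monocyte markers that passed. The mean of the monocyte list, CD14 included, was lower by 0.42 at T2, in 7 of 8 treated animals (exact permutation p = 0.0234, or 0.1375 adjusted over the lists). In controls it differed by 0.03, and the difference between the groups' changes did not pass (exact permutation p = 0.0597). THBS1 (-2.63, SE 0.503) fell among the platelet markers. The interferon-induced protease USP18 fell by 1.38 (SE 0.245), while XAF1 (0.34, SE 0.107) and MX1 (0.81, SE 0.280) rose. Of 45 oxidative phosphorylation genes 11 rose and 6 fell, a share near the 37.4% of all genes tested that changed in this comparison. NDUFS1 (0.75, SE 0.091) and UQCRC2 (0.58, SE 0.125) were higher and NDUFA5 (-0.43, SE 0.079) and NDUFA9 (-0.34, SE 0.067) lower. In lipid metabolism PLIN2, a coat protein of lipid droplets, fell by 1.32 (SE 0.203) and the receptor PPARD by 1.35 (SE 0.342), while ACADS (0.57, SE 0.136), HADHB (0.38, SE 0.094) and FDFT1 (0.39, SE 0.099) rose. In glycolysis HK1 (0.38, SE 0.080) and GPI (0.32, SE 0.094) rose and ENO1 (-0.41, SE 0.079) and the glucose transporter SLC2A3 (-0.85, SE 0.189) fell. The apoptosis genes CASP6 (0.57, SE 0.093) and BAX (0.51, SE 0.147) and the mitotic genes BIRC5 (1.01, SE 0.253) and CCNB2 (0.42, SE 0.151) rose. Of 39 ribosomal genes RPL27 fell by 0.91 (SE 0.154) and 3 rose, RPS18 (0.24, SE 0.078), RPL4 (0.36, SE 0.121) and RPLP0 (0.18, SE 0.066). XBP1 (-0.52, SE 0.083), DNAJB1 (-0.79, SE 0.254), the clock gene BHLHE40 (-0.66, SE 0.229), HDC (-0.49, SE 0.119) and LGMN (-0.42, SE 0.151) fell, and CATHL5 (0.74, SE 0.235), ID3 (0.76, SE 0.261) and BOLA-DMB (0.38, SE 0.126) rose. Of the housekeeping genes ACTB (0.39, SE 0.101) and PPIA (0.18, SE 0.053) rose and SDHA (-0.16, SE 0.062) fell. NR3C1 did not pass (0.03, SE 0.109). No list was called by camera, with the lowest adjusted p at 0.2421. With the animal as a block 1032 genes passed, 867 of them shared with the 916, while RPLP0 (adjusted p = 0.0805) and SDHA (adjusted p = 0.0979) no longer did. SLC5A1 (adjusted p = 0.0735), IL4 (0.0518) and SDHA (0.0505) did not pass with intensities under 16 raised to 16, and the fold of TLR5 became 1.40 and that of PPARD -0.95. With the mean of all features of a gene, MYD88 (0.18, adjusted p = 0.1755), CXCR4 (-1.78, adjusted p = 0.1799) and ZBTB16 (-0.44, adjusted p = 0.1008) did not pass, nor did IL4 (0.0509) and SDHA (0.0512). Without animals 28 and 32, 640 genes passed, and IL6, GADD45B, ZBTB16, IL18, CD3G, ID3, CATHL5, XAF1, BOLA-DMB, IL4, IL1B, BAX, RPS18, RPL4, RPLP0, DNAJB1, BHLHE40, HADHB, ITGB1 and SDHA did not, at adjusted p values from 0.0511 (XAF1) to 0.2823 (SDHA).

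Whether the treatment difference itself changed between T1 and T2 was tested by the interaction of treatment and time, and 223 genes moved up and 210 down in treated relative to control animals. Together they made up 17.7% of the genes tested. TLR5 moved up by 2.43 (SE 0.477, adjusted p = 0.0012), IL15 by 2.19 (SE 0.40, adjusted p = 6.92e-04) and NFE2 by 2.17 (SE 0.387, adjusted p = 5.44e-04), followed by TLR7 (1.95, SE 0.453), HRH1 (1.89, SE 0.616), the activin receptor ACVR1 (1.86, SE 0.373), EGR1 (1.85, SE 0.386), HNMT (1.79, SE 0.501), ASPH (1.65, SE 0.347) and FOS (1.64, SE 0.332). SPP1 moved by -7.03 (SE 1.236, adjusted p = 4.68e-04), CCL2 by -6.57 (SE 1.399, adjusted p = 0.0024), CXCL5 by -3.76 (SE 0.975, adjusted p = 0.0092) and CD14 by -2.55 (SE 0.482, adjusted p = 8.49e-04). CCL2 was dim or null in treated animals at T2, so the size of its fold is uncertain. SLC5A1 (-3.03, SE 0.578), THBS1 (-2.77, SE 0.644), TNFAIP6 (-1.97, SE 0.650), the urokinase receptor PLAUR (-1.95, SE 0.483), BASP1 (-1.79, SE 0.342) and CA4 (-1.76, SE 0.542) moved down as well. With intensities under 16 raised to 16, SLC5A1 (-0.62, adjusted p = 0.3106) and TNFAIP6 (-1.10, adjusted p = 0.1488) no longer passed, while SPP1, near the lowest intensities at T2, still did, with a fold of uncertain size. TLR5, ACVR1 and ASPH lay near that level in treated animals at T1, at 3.66, 3.79 and 4.0, so the size of their folds is uncertain as well, and with intensities raised TLR5 moved by 1.92 (adjusted p = 0.0016) and ACVR1 by 1.34 (adjusted p = 3.47e-04). Every treated animal with both values moved in the stated direction beyond the control mean for these 20 genes, except 1 of 8 for HRH1. Of them IL15 passed at both times in opposite directions, at -1.11 at T1 and 1.07 at T2 (SE 0.319).

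The trafficking list held 4 genes that moved down with treatment over time, CXCR4 (-1.47, SE 0.323, with differences of 0.88 at T1 and -0.58 at T2 that did not pass), CCR7 (-1.13, SE 0.268), CXCR5 (-1.08, SE 0.295) and the lymphocyte egress receptor S1PR1 (-0.84, SE 0.265), and 1 that moved up, of 12. Of 14 pattern recognition genes 3 moved up and 2 down, TIRAP (-0.93, SE 0.171) and CD14. ICOS (-0.91, SE 0.237), SLA (-0.66, SE 0.226), XBP1 (-0.49, SE 0.145), USP18 (-1.18, SE 0.379), RPL27 (-0.96, SE 0.198), PLIN2 (-1.13, SE 0.313) and NDUFA9 (-0.37, SE 0.090) moved down. JUN (0.93, SE 0.202), HK1 (0.57, SE 0.131), NDUFS1 (0.62, SE 0.177), CASP6 (0.42, SE 0.144) and the housekeeping gene ACTB (0.43, SE 0.139) moved up. ZBTB16 (-0.83, SE 0.417, adjusted p = 0.1696, 0.0361 with the animal as a block and 0.0419 with the mean of its features) and NR3C1 (0.35, SE 0.160, adjusted p = 0.1253, and 0.0206 with array weights) did not pass. No list was called by camera, the lowest adjusted p being 0.7396. With the animal as a block 625 genes passed, 335 up and 290 down, 422 of them shared with the 433. Without animals 28 and 32 the count fell from 433 to 224, and HRH1 (adjusted p = 0.0799), HNMT (0.0623), TNFAIP6 (0.0679), CA4 (0.1351), XBP1 (0.0765), USP18 (0.0948), CASP6 (0.1224), NDUFS1 (0.0623), PLIN2 (0.0583), S1PR1 (0.1080) and ACTB (0.0821) no longer passed. With quantile normalization 370 genes moved up and 96 down, around a median of all genes that this scaling shifted to 0.16, and the values as deposited gave 191 and 240.

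Across the 2446 genes the treatment differences at T1 and T2 correlated at Pearson's r = -0.24 and Spearman's rho = -0.20, and 44.2% of genes had the same sign at both times; genes are not independent replicates. Both comparisons hold the same animals, so animal differences alone give a correlation above 0: in 100 relabellings of the animals r had a median of 0.29 and ranged from -0.01 to 0.64, never as low as observed. The correlation weakened to -0.07 without animals 28 and 32, a setting in which no relabellings were run. Of the genes that passed, 2 did so at both T1 and T2, 1 lower at both times and 1 in opposite directions.

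**Figure D3:**
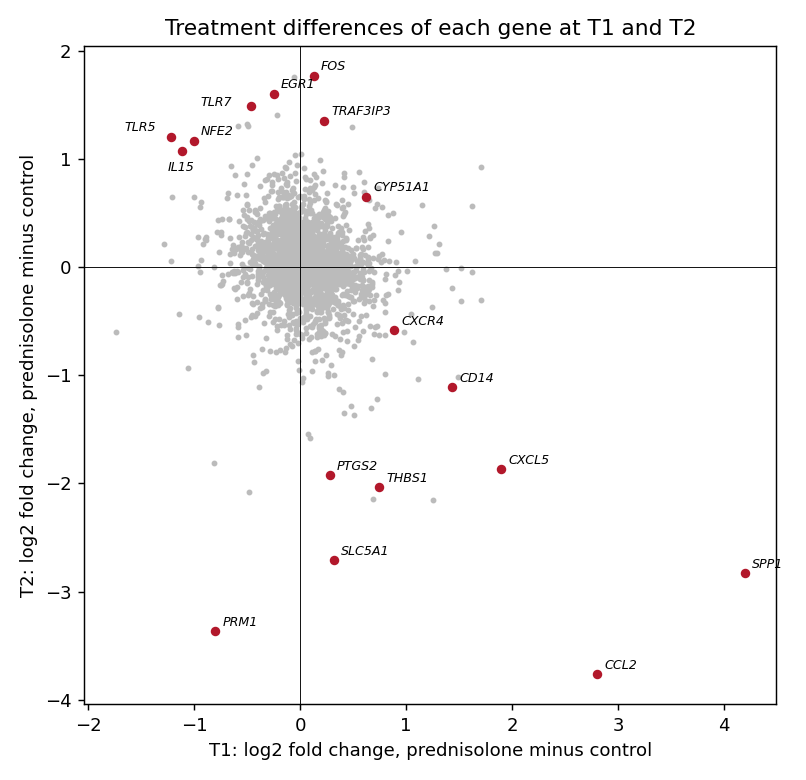
Treatment difference (log2 fold change, prednisolone minus control) of each of the 2446 genes at T1 (horizontal) and T2 (vertical); each point is 1 gene and named genes are red. SPP1 and CCL2 lie at 4.20 and 2.80 at T1 and at -2.83 and -3.76 at T2, while TLR5 and IL15 lie below 0 at T1 and above 0 at T2.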

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

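The tests on monocyte markers, platelet markers and quickly induced cytokines below, the probe pairs of the genes that passed at T2, and the values without animals 28 and 32, were chosen only after the results were seen.

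For treatment at T1, 7 genes passed, against at most 1 in other relabellings of the animals, and 1 of 100 relabellings, the real one, reached 7. For treatment at T2 (445 against at most 117), over both times (55 against at most 1) and by time (433 against at most 125), again only the real labels, 1 of 100, reached the count, as for T2 against T1 in treated animals (916 against at most 324 in within-animal swaps, 1 of 100). A share of 1 in 100 is the smallest that 100 labellings allow. It makes a random split unlikely as the source of these 5 counts but does not exclude it. The count of 7 at T1 was also fragile, at 0 without the filter on dim genes and 0 without animals 28 and 32. In controls no gene passed, a count that every one of the 64 swaps reaches by construction (0, the highest other being 1), so the swaps say nothing about chance there.

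The treatment difference at T2 covered 445 genes and was weighed against technical causes. With each array's number of null features as a covariate, 384 of the 445 genes still passed, though CCL2 (adjusted p = 0.1144), CD14 (adjusted p = 0.0550) and PLAUR (adjusted p = 0.0563) did not. That argues against the number of null features as their whole cause. It says little of other traits of array quality, since null features overlapped widely at T2 (6572 to 9901 in controls, 6145 to 9726 in treated animals). The scaling shift, which was not tested, overlapped less, at -0.0294 to 0.0275 in controls and 0.0099 to 0.044 in treated animals. In 69 genes with a pair of distinct probes, the T2 differences of both probes correlated at 0.459 across genes (95% bootstrap interval 0.212 to 0.659), and 41 had the same sign. The highest correlation in shuffled genes was 0.430, so the probes shared more than shuffling gives. The correlation missed the bound set beforehand, above 0.5 with an interval above 0.2. In the 16 of these genes that passed at T2 it was 0.557, with 12 of the same sign, but its interval of 0.076 to 0.893 missed that bound too, so hybridisation particular to single probes stays open. A slide or batch effect that follows the groups, a drug effect and other differences between the groups' animals stay open, since no label names the slides.

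CD14, CCL2, SPP1, THBS1 and PLAUR were lower in treated animals at T2. Fewer monocytes in the preparations would lower the other monocyte markers too, as far as monocytes are their source. The 7 others, among them the bright TYROBP, CTSB, AIF1 and CTSS, had a median T2 difference of 0.000 (SD 0.139) beside -1.11 for CD14. CTSS is also in the MHC class II list, and bright neutrophil transcripts were present, so other cells may hold part of these signals. Fewer platelets would lower ITGA2B, ITGB3 and SELP with THBS1, but their median was 0.255 (SD 0.170) beside -2.03. The platelet median argues against a loss of platelets as the whole cause at T2, from 3 markers alone. The monocyte median shows that these 7 markers did not fall with CD14. It cannot decide on a loss of monocytes, in part or as the whole cause, since the share of other cells in these signals was not measured. In treated animals the mean of the monocyte list, CD14 included, was lower by 0.42 at T2 than at T1, in 7 of 8 (exact permutation p = 0.0234, or 0.1375 adjusted over the lists). CD14 itself lay at -2.33 in that comparison, and the 7 others lay at -0.40 (FCER1G) to 0.33 (CTSS). This mean therefore rests in large part on CD14, the gene in question. A drug effect on transcription within monocytes or platelets may account for the pattern, as an untested hypothesis, and array quality stays open as part of the cause for CCL2, which went from -3.76 (SE 0.887) to -2.45 (SE 0.983) with the covariate. CD14 went from -1.11 (SE 0.339) to -0.91 (SE 0.312) and PLAUR from -1.22 (SE 0.369) to -1.12 (SE 0.386), moves within their SE that ended the calls just past the threshold.

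FOS, EGR1, JUN and ZFP36 were higher in treated animals at T2. Activation of cells during handling could raise such genes, and would raise IL1B, TNF, CXCL8, CCL3 and CXCL2 with them. These 5 had a median T2 difference of -0.659 with an SD of 0.844. IL1B (-0.96), TNF (-0.66), CXCL8 (-0.09) and CCL3 (-0.95) were lower, and of these only CCL3 passed (adjusted p = 0.0201). CXCL2 alone was higher, at 1.05, and did not pass (adjusted p = 0.2016). The median lay below 0 by less than the SD, so handling and a drug effect cannot be told apart.

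The interaction of treatment and time stood out because it tests a difference between times directly. It held for 433 genes. Among the named genes the changes were 2.43 for TLR5, 2.19 for IL15, 2.17 for NFE2, 1.95 for TLR7, 1.89 for HRH1, 1.86 for ACVR1, 1.85 for EGR1, 1.79 for HNMT, 1.65 for ASPH, 1.64 for FOS, 0.93 for JUN, 0.62 for NDUFS1, 0.57 for HK1, 0.43 for ACTB and 0.42 for CASP6. Downward they were -7.03 for SPP1, -6.57 for CCL2, -3.76 for CXCL5, -3.03 for SLC5A1, -2.77 for THBS1, -2.55 for CD14, -1.97 for TNFAIP6, -1.95 for PLAUR, -1.79 for BASP1, -1.76 for CA4, -1.47 for CXCR4, -1.18 for USP18, -1.13 for CCR7 and for PLIN2, -1.08 for CXCR5, -0.96 for RPL27, -0.93 for TIRAP, -0.91 for ICOS, -0.84 for S1PR1, -0.66 for SLA, -0.49 for XBP1 and -0.37 for NDUFA9. SLC5A1 (-0.62, adjusted p = 0.3106) and TNFAIP6 (-1.10, adjusted p = 0.1488) did not pass with intensities under 16 raised to 16, and SPP1 at T2 and TLR5, ACVR1 and ASPH at T1 in treated animals lay near the lowest intensities. CCL2 was dim or null in treated animals at T2. With the animal as a block 625 genes passed. Without animals 28 and 32, 224 passed, and HRH1, HNMT, TNFAIP6, CA4, XBP1, USP18, CASP6, NDUFS1, PLIN2, S1PR1 and ACTB did not.

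Features without a gene name entered none of the comparisons above. Tested one by one, 290 of 25045 passed for treatment at T1, 4947 at T2, 792 over both times, 9932 for T2 against T1 in treated animals and 4793 by time, while none passed in controls in limma, where 3244 of all 30011 features had an unadjusted p under 0.05. At T2 that was 19.8% of the unnamed features beside 17.3% of the named ones.

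Single animals far from the rest of their group were sought with Dixon's test, which by chance marks about 1 in 20 groups: 34 of 504 gene groups stood out where 25.2 were expected, 4 of 88 list groups where 4.4 were, and 1 of 20 array groups where 1 was. All values are log2 intensities unless stated. In treated animal 26 at T2 the interferon response list lay at 1.96 relative to the mean of all arrays (others -0.40 to 0.33), with USP18 at 11.38, XAF1 at 13.79, COL6A2 at 8.74, COX7C at 13.61 and ENO1 at 5.63. In treated animal 30 at T1 the heat shock list lay at 1.85 (others -0.16 to 0.34), with AHSA1 at 12.80 and DNAJB1 at 12.63. Treated animal 28 at T1 had BOLA-DYB at 6.30, CR2 at 5.89, HMMR at 3.97, NR3C1 at 12.61 and TNFAIP6 at 7.60, and IL15 at 5.60 at T2. Other treated animals stood out for CCL3 (8.32) and PPARD (1.92), both in animal 29 at T2, DNAJB1 (10.81, animal 25 at T2) and IFNG (7.74, animal 29 at T1). Control animal 23 at T2 had ACTB at 16.50, COX7C at 13.23, CXCR4 at 12.22, HMGB2 at 13.48, NR3C1 at 12.11 and ZBTB43 at 10.41. Control animal 18 had GAL at 12.05, HK1 at 12.51, SDHA at 14.48, the trafficking list at -0.39 and the housekeeping list at -0.24 at T2, and S1PR1 at 8.42 and XBP1 at 13.89 at T1. Control animal 17 at T1 had ACTB at 17.20, GRO1 at 12.24, ITGB1 at 12.52 and a median intensity of 996.7 (others 1015 to 1027). PTGS2 lay at 11.29 in control animal 22 at T2 (others 7.64 to 9.06), CXCR5 at 4.37 in control animal 22 at T1 and RPL4 at 13.07 in control animal 20 at T1.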

How the results depend on the processing

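The values with null features as a covariate, quantile normalization over complete features, the values as deposited, the brightest feature alone, intensities raised to 16, and without animals 28 and 32 or, for lists, 30 were chosen only after the data were seen. Among the named genes and lists no called value changed direction under the settings compared, and 40 values that were not called changed sign. Directions were not compared with every feature by itself. Of the 16 genes that passed at T2 and had a pair of distinct probes, 12 had both probes on the same sign. Of 174 calls of named genes, the animal block ended 16, quantile normalization 29, no filter on dim genes 25, array weights 11, the covariate 11 and leaving out animals 28 and 32 together 55, and the removal of single animals ended between 7 (animal 20) and 40 (animal 28). The cause was not tested unless stated.

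The count for treatment at T1 (7) became 118 with quantile normalization, 46 with it over complete features, 0 without a dim-gene filter, 44 with more dim genes left out, 324 with every feature by itself, 69 with array weights, 4 with a trended robust fit, 233 with the block, 252 in 1 fit of 30 arrays, 191 with the covariate, 0 without animals 28 and 32 and 1 at a fold of at least 2. Over both times 55 became 15 and 87 with those scalings, 32 without the filter, 90 with fewer genes, 909 by feature, 87 with the block, 19 without animals 28 and 32 and 0 at that fold. In controls 0 became 12, 2 and 3 with quantile normalization, weights and the block. Every feature by itself, by construction of 30011 tests, gave 5807 at T2, 11797 for T2 against T1 in treated and 5602 for treatment by time; the fold threshold gave 30, 106 and 87. The interaction gave 224, and the agreement of T1 and T2 -0.071, without animals 28 and 32. Lists called numbered 1 instead of 0 at T1 and 2 instead of 0 in controls with quantile normalization, 1 in controls with the block, 1 instead of 2 at T2 with quantile normalization, and 0 at T2 and over both times with an estimated correlation; no list call changed without animal 30, and without animals 28 and 32 it was 1 instead of 0 at T1, the glucocorticoid-repressed list, a call not made with an estimated correlation (adjusted p = 0.8488) or by its exact permutation test (p = 0.2273). Over both times quantile normalization ended camera's call of the ribosomal list (adjusted p = 0.1818) and gained that of the cholesterol synthesis list (adjusted p = 0.0495). It moved the median of all genes to -0.094 at T1, 0.081 at T2, -0.126 in the control time comparison and 0.162 in the interaction.

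Leaving out 1 animal gave 0 to 107 genes at T1: 107 without animal 17, 58 without 26, 34 without 25, 20 without 20, 11 without 29, 1 without 18 or 31 and 0 without 21, 22, 23, 27, 28, 30 or 32. Over both times it gave 16 (without 22) to 88 (without 20), with 24 without 18, 27 without 24 or 30, 25 without 26, 32 without 27, 34 without 28 and 21 without 29. In controls it gave 0 to 2 (without 17), at T2 324 to 482, in treated animals 768 to 924 and by time 328 to 481.

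Quantile normalization ended the calls of TNFAIP6, NFKBIA, SLA, IL2, CD2, CXCR5, NDUFS1, HSPA5 and TIRAP at T2, of FOS, HDHD3, NPFF, FBXO8 and CD2 over both times, of CD2, HDC, LGMN, IL4, RPS18, RPLP0, HADHB, ENO1 and PPIA in treated animals over time, and of TNFAIP6, SLA, CXCR5, ICOS, S1PR1 and TIRAP by time, at adjusted p values from 0.0523 (FOS) to 0.2865 (CXCR5 at T2). The values as deposited ended those of CD2, NCR1, NDUFS1, NDUFA6, HSPA5 and ACADVL at T2, of CCNB2, RPS18, RPL4, RPLP0 and PPIA in treated animals and of CASP6 by time, at 0.0508 (NCR1) to 0.1181 (RPLP0). The brightest feature alone ended those of ARNT and HMGB2 at T1, TNFAIP6, CD2, NDUFS1 and NDUFA6 at T2, CD2 over both times, CD40LG, IL4, RPS18, RPL4 and RPLP0 in treated animals and CASP6 and ACTB by time, at 0.0507 (CASP6) to 0.2852 (NDUFA6).

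Without the filter on dim genes all 7 calls at T1 ended, with those of HRH1, CEBPD, SLA, CD2, NCR1, NDUFS1, NDUFA6 and HSPA5 at T2, HDHD3 and CD2 over both times, IL6, IL4, LGMN, CCNB2, RPLP0 and SDHA in treated animals and SLA and CASP6 by time, at 0.0503 (SLA at T2) to 0.0715 (SDHA). Array weights ended those of GRO1, HRH1 and CEBPD at T2, ID3, IL1B, CCNB2, RPS18, RPL4, RPLP0 and SDHA in treated animals and ACTB by time, at 0.0517 (RPL4) to 0.1205 (RPLP0). The covariate ended those of CCL2, CD14, HRH1, TNFAIP6, CD2, NDUFS1 and HADHA at T2, IL6 and SDHA in treated animals and TNFAIP6 and USP18 by time, at 0.0506 (HADHA) to 0.1144 (CCL2). A trended robust fit ended those of IL15, ARNT and AMY2B at T1, NDUFS1 at T2 and IL4 in treated animals (0.0501 to 0.0547), and quantile normalization over complete features those of NDUFA6 and HSPA5 at T2 and BIRC5, RPLP0 and PPIA in treated animals (0.0522 to 0.1181). Calls were gained as well: over both times CEBPD (0.0277), MX1 (0.0332) and HADHA (0.0296) passed with the block and IL2 with the covariate (0.0319), and in controls IFITM1 (0.0263) with weights, BIRC5 (0.0316) with the block and SLA, ZBTB43, COL6A2 and DNAJB1 with quantile normalization. At T1 the block gained those of SPP1, CD14, CXCR4, TIRAP, TLR5, COX7C, XBP1, CYP51A1, HK1, LDHA, MECR and GAL. A single fit of all 30 arrays without the block gained the same calls, so they do not rest on the block itself. Several of these genes also passed at T1 with quantile normalization, array weights or the covariate, CD14 at 0.0307, 0.0339 and 0.0174. With array weights IFNG (0.0376) and BOLA-DYB (0.0376) passed at T1.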

Other observations

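The genes and values in this part were chosen only after they were seen. The lymphocyte preparations held bright transcripts of other blood cells in every group. The haemoglobin genes HBB and HBG lay at 17.16 ± 0.94 and 17.92 ± 0.69 in controls at T2 (SD, n = 7) and at 17.38 ± 0.69 and 18.18 ± 0.49 in treated animals (SD, n = 8). S100A12, abundant in neutrophils, lay at 17.21 ± 0.32 (SD, n = 7) and 17.13 ± 0.30 (SD, n = 8). None of the 3 passed at T1 or T2 (log2 differences at T2 of 0.22, 0.25 and -0.08). The erythroid and neutrophil lists were not called in any comparison, with camera's adjusted p at T2 of 0.9032 and 0.7686. Over time in treated animals the mean of the erythroid list was higher by 0.54 at T2, in 7 of 8 animals (exact permutation p = 0.0391, or 0.1432 adjusted over the lists), and HBB went from 16.57 ± 0.97 (SD, n = 8) to 17.38 ± 0.69 (SD, n = 8). In controls the list was higher too, by 0.21 in 5 of 7 animals, with HBB going from 16.80 ± 1.19 (SD, n = 7) to 17.16 ± 0.94 (SD, n = 7), and the groups' changes did not differ past the threshold (exact permutation p = 0.1975).

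Of the 445 genes that passed at T2 and the 916 that changed over time in treated animals, 370 were shared, 220 higher and 150 lower in both, where independent calls would give 56.56 and 29.03. Both comparisons use the treated arrays of T2, so they are not independent. Between animals, the median gene's SD was 0.205 in treated animals at T2, beside 0.240 in controls at T2, 0.255 in treated animals at T1 and 0.260 in controls at T1. HSPA1A, the inducible heat shock protein 70, lay at 9.84 ± 2.27 in treated animals at T1 (SD, n = 8) beside 8.55 ± 0.29 in controls (SD, n = 7), with 15.29 in animal 30. Without animal 30 the heat shock list was still called by camera at T2 (median 0.24, adjusted p = 0.0344) and over both times (median 0.16, adjusted p = 0.0195), against adjusted p = 0.9652 and adjusted p = 0.3707 with an estimated correlation.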
